A study of Brassica oleracea with 107 samples.

How the data were processed

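RNA was sequenced from 107 libraries of Brassica oleracea seed, 45 of embryo and 62 of endosperm. Per the labels' protocols, plants were kept at 21 °C until bolting and at 16 °C until the embryo reached the bent-cotyledon stage, and were then held at 16 °C or at 26 °C. Embryo and endosperm were separated by dissection under a microscope, and the fraction called endosperm also held the seed coat. A recovery group was moved from 26 °C to 16 °C; the day of the move is not given in the sources used here. The labels put the libraries in 36 groups by tissue, temperature and time. Each group had 3 libraries except endosperm at 16 °C on day 18, which had 2.

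Per the labels' protocols, endosperm libraries of days 7, 15, 18 and 22 were made with the Ovation RNA-seq system and the rest with a standard Illumina protocol. Kit and day therefore change together in endosperm. For this reason the endosperm values were handled in 3 sets: days 0 to 3, days 7 to 22, and the series labelled in hours. None of the 28 comparisons crosses these sets. Some values added after the data were examined do: the genes that differ between library kits, the late genes of days 7 to 22 set beside the hour series, and single identifiers followed across the sets. In these, kit and time cannot be separated, except between days 0 to 3 and the hour series, which share the standard kit. The overlaps and correlations between tissues also set standard-kit embryo beside Ovation endosperm from day 7 on. Embryo was 1 set. The labels do not say from which event the hours or days are counted; the series title names both seed development and germination.

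The values were used as the authors deposited them, in TPM (a transcript abundance: a read count divided by gene length and scaled so that the genes of a library sum to 1000000). Per the submitters' processing notes, the tools included cutadapt 1.9.1, STAR 2.5 and featureCounts; the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Each of the 2 deposited tables, 1 per tissue, holds 1 column per group, so the values of the separate libraries are not analysed here and how the authors combined them is not stated. The tables are named for differentially expressed genes, so the genes are ones the authors selected, by a rule that is not given in the sources used here. For embryo 13120 genes are listed and for endosperm 16338 genes, of which 9726 are in both. The listed values of a column sum to between 47.0% and 76.7% of 1000000 TPM, which means that TPM was scaled over more genes than are listed. A list chosen by its authors on these samples is not independent evidence that genes differ between these groups.

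TPM keeps no record of depth, so the number of reads behind a value is unknown, and neither a counting interval nor a detection limit is given. With 1 value per group there is no SD and no n, and a difference between columns has no replicate check. The tests fixed before the data were examined (limma on log2 values with Benjamini-Hochberg adjustment, and fry on gene lists) need values per library and could not be run, so no p-value is given. In their place a rule of size was used: a gene was counted as higher or lower when 2 columns differed by at least 2-fold on the log2(TPM + 1) scale. This scale understates the change of genes with low values. Genes under 1 TPM in every column of a set were left out of that set, 1 column standing for the 3 libraries of the planned filter. This left 11899 embryo genes, and 12604, 14601 and 13203 endosperm genes for days 0 to 3, days 7 to 22 and the hour series. The 28 comparisons are those fixed beforehand: 26 °C against 16 °C at each time, recovery against each temperature, the 16 °C course within a set, and the difference of the temperature effect between a late and an early day.

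None of the 19732 gene identifiers matched the 53125 genes of the reference gene table used here, and the deposited tables pair no identifier with a gene name. The 22 gene lists fixed beforehand, among them abscisic acid, gibberellin, dormancy and storage protein genes, could therefore not be looked up, and no gene is named by function. The rule for identifiers was at most 2 higher and 2 lower per comparison, which were taken as those with the largest log2 difference among genes at 5 TPM or more in the higher column. Identifiers printed outside that rule were chosen after their values were seen, and this is said where they appear.

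Several measures were added after the data were examined. The position of a column on the 16 °C course is the time at which the straight lines joining consecutive 16 °C columns pass nearest to it, by root-mean-square log2 distance over all genes of the set; its range is given over 10 random subsets of the genes and describes agreement between genes, not between plants. Genes were also grouped by a difference of at least 4-fold between the first and last 16 °C column of a set, and overlaps of gene counts between comparisons are set beside the number that independent lists would share. The genes followed into recovery were chosen on day 15 and measured on days 18 and 22.

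The alternatives run were a pseudocount of 0.1, no filter on low values, and median centring of each column on the genes at 1 TPM or more in all columns of the set. A further 2 were chosen after seeing the data: rescaling without the 10 most abundant genes of a set, and an exchange of the endosperm columns labelled 26 °C and recovery on day 18. The counting rule was tested on simulated data made from the embryo 16 °C column of day 1, with 200 of 9899 genes changed 4-fold and random noise with an SD of 0.1 log2 units. It recovered 200 of the 200 and counted 0 of the 9699 unchanged genes. A simulated embryo column placed at day 11 was positioned at 10.97. With noise this small the test checks the calculation alone and gives no error rate of the 2-fold rule between real libraries. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.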

Results

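Transcript abundance was measured by RNA sequencing in the embryo and in the endosperm with seed coat of Brassica oleracea, the species of cabbage and broccoli, in seeds held at 16 °C, at 26 °C or returned from 26 °C to 16 °C. Embryo was sampled on days 0, 1, 3, 7, 15, 18 and 22. Endosperm was sampled on the same days and in a further series at hours 1, 24 and 72. Day 0 was sampled at 16 °C alone, and recovery on days 18 and 22. The design asks how temperature alters the seed transcriptome over time in each tissue. Values are the authors' TPM, 1 per group, with no replicate values, so none of the differences reported here has a replicate check. The genes are those the authors listed, and sequencing depth is unknown. Counts of genes refer to differences of at least 2-fold on the log2(TPM + 1) scale, and genes are given by the identifiers of the deposited tables. Of the 28 counts, 19 were more than 1.5 times higher with a pseudocount of 0.1, which gives more weight to genes with low values.

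Embryo columns at 16 °C were compared over time. Between days 0 and 1, 61 of 11899 genes differed 2-fold, the smallest number between neighbouring 16 °C embryo columns, which lie 1 to 8 days apart. The number was 371 between days 1 and 3, 384 between days 3 and 7, 1571 between days 7 and 15, 361 between days 15 and 18 and 796 between days 18 and 22. From day 0 to day 22, 1286 genes were higher and 5598 lower. The median gene was lower on day 22, by a log2 difference of -0.90, while a few genes took a growing share of the transcripts. After median centring the split was 2832 higher and 2787 lower, and after rescaling without the 10 most abundant genes it was 1887 and 4449. The 2 genes with the largest gain were Bo1g086230, at 0.04 TPM on day 0 and 2465 TPM on day 22, and Bo1g058990, listed at 0 on day 0 and at 1647 TPM on day 22. Bo3g175350 was at 845 TPM on day 0 and 1.36 TPM on day 22, and Bo2g149980 at 932 and 2.59 TPM. The 10 most abundant genes of each column held 13.0% of all TPM on day 0 and 44.7% on day 18 at 16 °C. Bo7g111280, singled out after its values were seen as the gene with the highest embryo value, was at 26200 TPM on day 0 and 145316 TPM on day 18.

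Embryos at 26 °C differed from those at 16 °C from the first day, with more genes higher than lower at 26 °C. On day 1, 1102 genes were higher at 26 °C and 468 lower. On day 3 the numbers were 646 and 94, and on day 7 they were 1023 and 254. The excess of higher genes was smaller after median centring, with 828 and 734 on day 1, 399 and 201 on day 3, and 789 and 429 on day 7. Bo3g044590 was at 221 TPM at 26 °C and 1.02 TPM at 16 °C on day 1, and at 125 and 2.23 TPM on day 3. Bo3g004380 was at 127 TPM at 26 °C and 0.11 TPM at 16 °C on day 1. Bo3g028030 was lower at 26 °C on day 1, at 2.39 TPM against 77.1 TPM. On day 7, Bo2g086460 was at 2434 TPM at 26 °C and 45.6 TPM at 16 °C, and Bo8g108390 at 0.83 and 24.5 TPM.

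From day 15 the embryo lists were larger and held many genes that were lower at 26 °C. On day 15, 1240 genes were higher and 1715 lower, and on day 18 the numbers were 1678 and 2234. The direction of the day 18 split depended on the scaling, with 1942 higher and 1899 lower after median centring and 1519 and 3403 after rescaling without the 10 most abundant genes. On day 22, 3088 genes were higher and 1783 lower. That split did too, with 2398 higher and 2418 lower after median centring and 2256 and 3012 after rescaling. Bo1g050780 was at 251 TPM at 26 °C and 1.35 TPM at 16 °C on day 15, and at 1342 and 27.7 TPM on day 22, when Bo3g167210 was at 124 and 0.58 TPM. Bo3g035510 was at 4092 TPM at 26 °C and 10.6 TPM at 16 °C on day 18. The gene with the largest deficit at 26 °C was Bo5g017210 on day 15, at 1.71 against 119 TPM, Bo7g116690 on day 18, at 0.05 against 22.7 TPM, and Bo4g173640 on day 22, at 1.98 against 323 TPM. Bo7g044900 was among the 2 genes with the largest deficit at 26 °C on days 15, 18 and 22, at 9.48 against 395 TPM, 7.72 against 154 TPM and 0.24 against 67.1 TPM. The most abundant genes held less of the transcripts at 26 °C on day 22, where the top 10 took 20.2% of TPM against 40.9% at 16 °C. Bo7g111280 was at 14479 TPM at 26 °C and 106974 TPM at 16 °C on that day. The temperature difference of day 22 minus that of day 1 was at least 2-fold upward for 2626 genes and downward for 2262. This turned to 2315 and 2511 after median centring, to 1914 and 3322 after rescaling and to 3445 and 3572 with a pseudocount of 0.1.

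**Figure D1:**
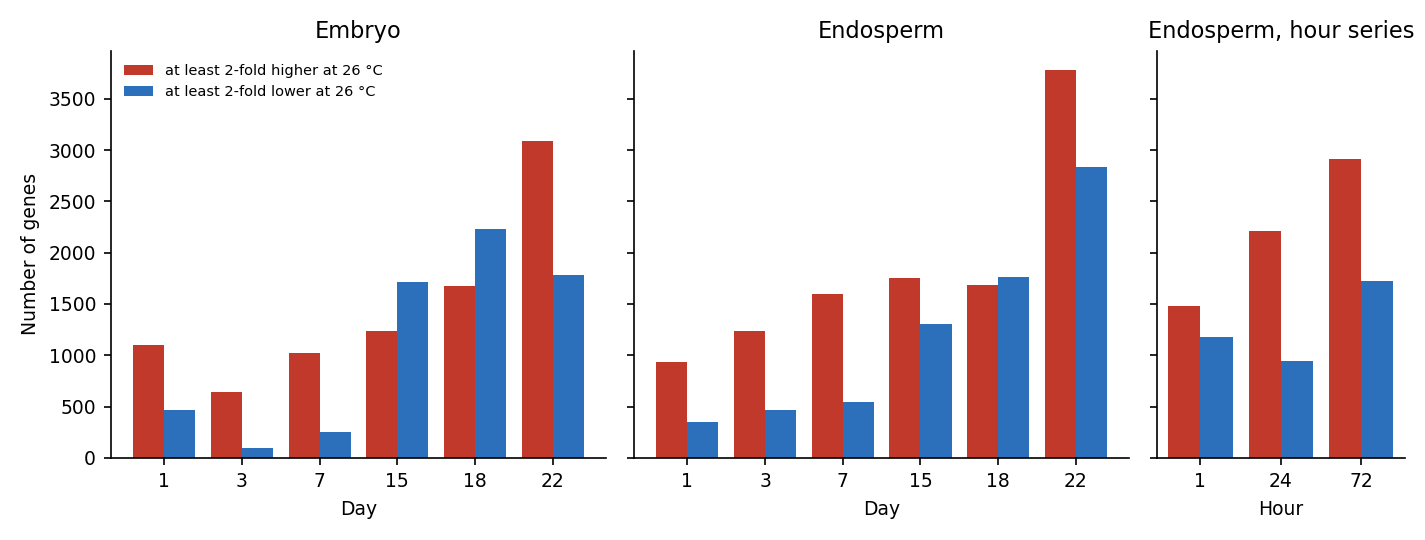
Number of genes at least 2-fold higher (red) or lower (blue) at 26 °C than at 16 °C, by sampling time in days or hours, for embryo, endosperm and the endosperm hour series; each bar is a count of genes from 1 pair of group values. In embryo the higher genes go from 1102 on day 1 to 3088 on day 22; endosperm days 1 and 3 (of 12604 genes) and days 7 to 22 (of 14601 genes) were made with different library kits, and their bars are not compared with each other.

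Genes that separated late from early embryos at 16 °C were followed at 26 °C on days 1 to 18. The 599 genes at least 4-fold higher at 16 °C on day 22 than on day 0 were taken first. On day 1, 114 (19.0%) were 2-fold higher at 26 °C and 5 lower, and on day 3 there were 111 and 10. On day 7, 254 (42.4%) were higher and 7 lower, on day 15 there were 298 and 49, and on day 18 there were 353 (58.9%) and 51. Of the 2563 genes at least 4-fold lower on day 22 than on day 0, 284 were lower at 26 °C on day 1 and 117 higher. On day 3 more were higher than lower, with 72 and 44. On day 7, 189 (7.4%) were lower and 42 higher, on day 15 there were 898 (35.0%) and 54, and on day 18 there were 996 (38.9%) and 77. Of the 2542 genes within 0.5 log2 units between days 0 and 22, 264 were higher and 9 lower at 26 °C on day 7, and 427 (16.8%) were higher and 248 (9.8%) lower on day 18. These gene groups were chosen on columns not used in the temperature differences given.

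**Figure D2:**
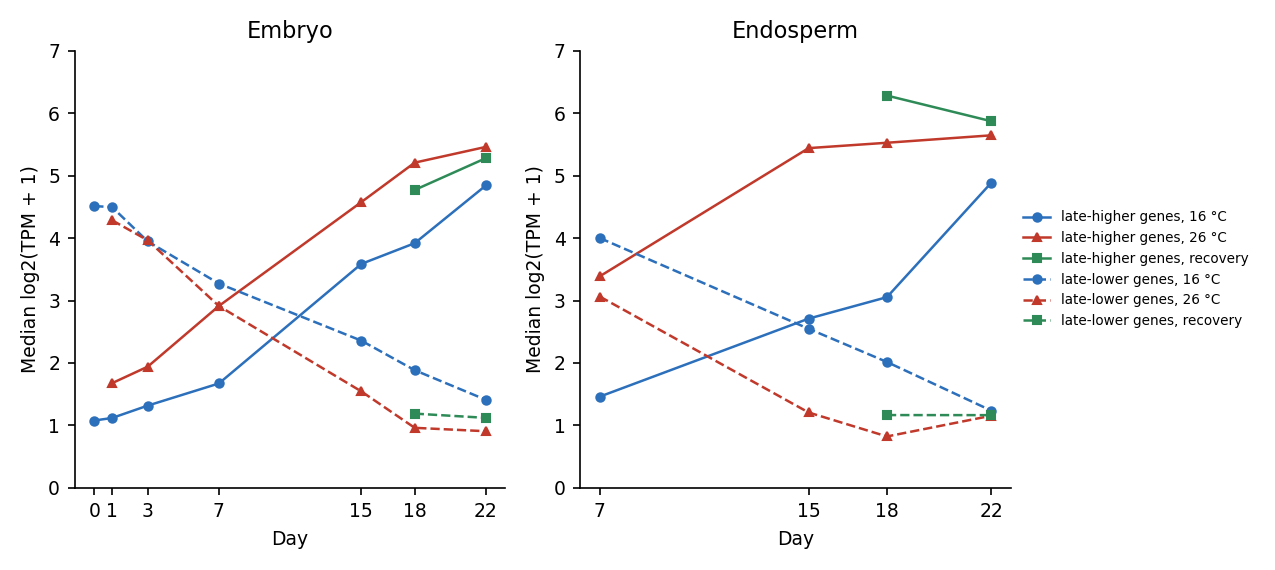
Median log2(TPM + 1) by day for genes at least 4-fold higher (solid lines) or lower (dashed lines) on the last than on the first 16 °C day of the set, at 16 °C (blue), 26 °C (red) and recovery (green), in embryo (599 and 2563 genes) and endosperm (425 and 297 genes). On day 15 the late-higher embryo genes had a median of 4.58 at 26 °C and 3.59 at 16 °C.

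Placed on the 16 °C course by the values of all genes, the embryo column of day 7 at 26 °C lay at day 11.2, with a range of 10.9 to 11.6 over 10 random subsets of the genes. The column of day 15 at 26 °C lay at day 21.3 (range 21.0 to 21.4). The columns of days 18 and 22 at 26 °C lay at the last 16 °C column, day 22, beyond which no position can be given. On day 3 the position was 2.79, but 4.14 after median centring and 3.63 after rescaling, so its side of the sampling day depended on the scaling. On day 1 it was not well set, at 0.05 with a range of 0 to 1.94. The nearest 16 °C point still left a distance: 359 genes (3.0%) of the embryo on day 15 at 26 °C lay 2-fold outside the range of all 7 columns at 16 °C, against 2 genes for the 16 °C column of day 15 and 579 genes (4.87%) for that of day 22, each set against the other 16 °C columns. On day 22 at 26 °C, 2896 genes (24.3%) lay outside. Of these, 1575 were above and 1321 below.

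**Figure D3:**
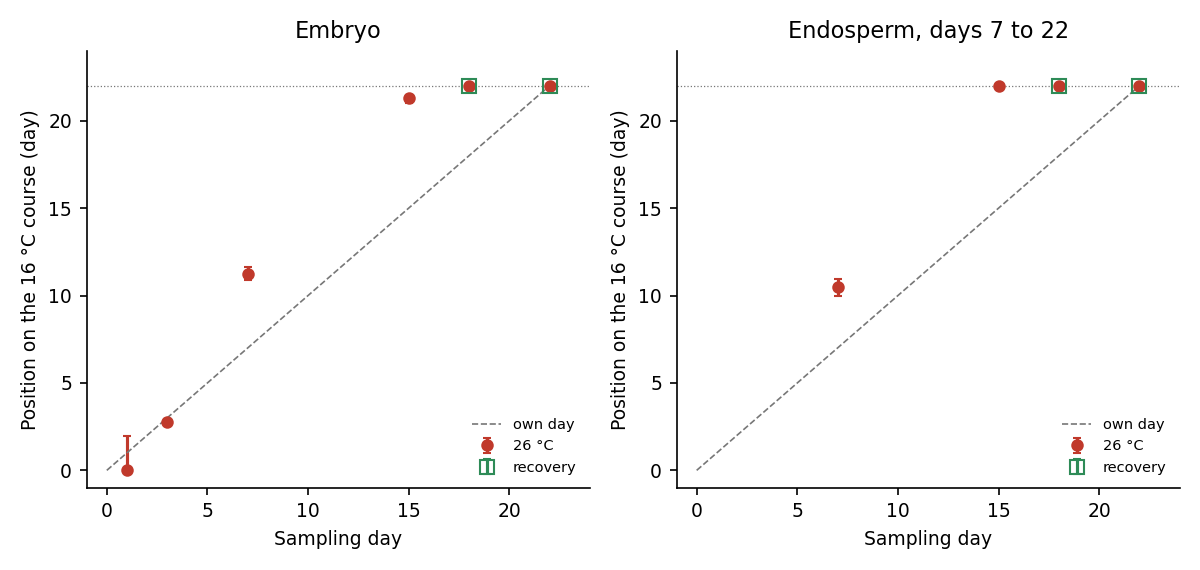
Position of each 26 °C column (red circles) and recovery column (green squares) on the 16 °C course, in days, against the sampling day; error bars span 10 random subsets of the genes, the dashed line marks the sampling day and the dotted line the last 16 °C day. In embryo the 26 °C column of day 7 lies at 11.2 and that of day 15 at 21.3; in endosperm that of day 7 lies at 10.5.

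In endosperm at 16 °C, days 0 to 3 differed little. Of 12604 genes, 166 were higher and 82 lower on day 3 than on day 0, or 208 and 53 after median centring. From day 7 to day 22, 1106 of 14601 genes were higher and 2031 lower, or 1327 and 1483 after centring. Bo6g119910 was at 1.59 TPM on day 7 and 1003 TPM on day 22, while Bo2g131830 was at 171 and 1.11 TPM and Bo2g131820 at 3252 and 52.7 TPM. Days 3 and 7 were not compared, since the library kit differs between them. The size of that step can be seen in 2 genes singled out after their values were seen, as the genes with the highest endosperm values. Bo4g163690 was between 2756 and 6773 TPM on days 0 to 3, between 93422 and 304654 TPM on days 7 to 22, and between 411 and 9711 TPM in the hour series. Bo8g106030 was at no more than 4.84 TPM on days 0 to 3, between 9254 and 90480 TPM on days 7 to 22, and at no more than 27.0 TPM in the hour series.

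**Figure D4:**
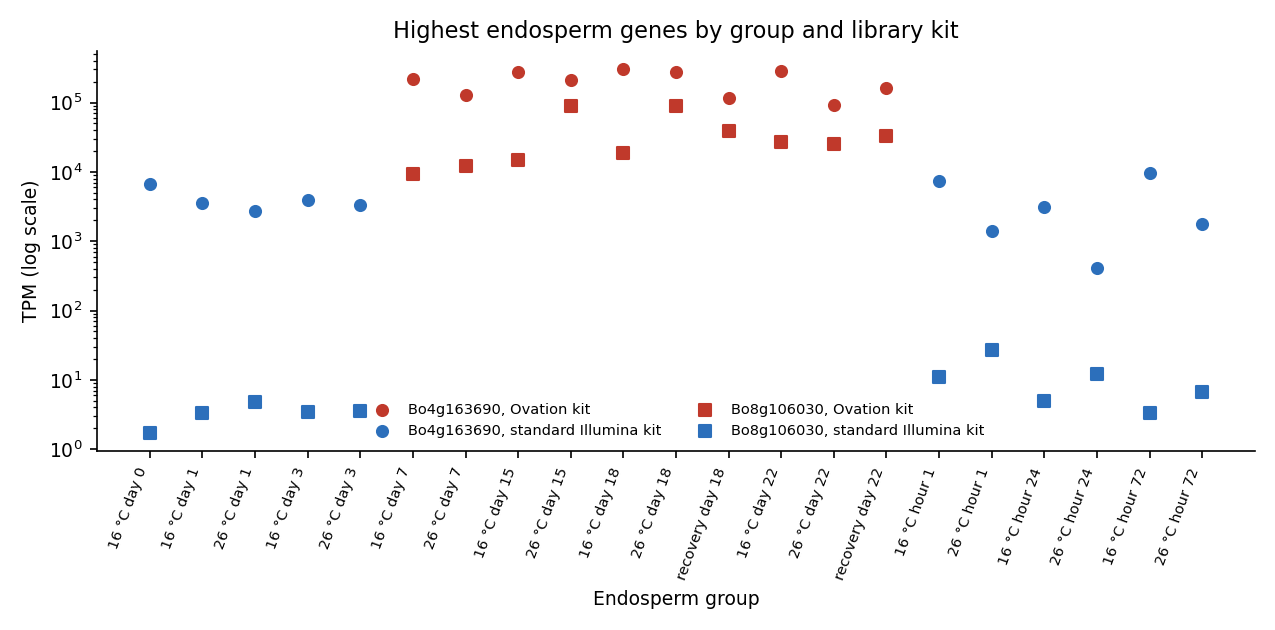
TPM on a log scale of Bo4g163690 (circles) and Bo8g106030 (squares) in each endosperm group, coloured by library kit (red, Ovation; blue, standard Illumina); each point is 1 deposited group value. Bo8g106030 lies between 9254 and 90480 TPM in the Ovation groups and at or below 27.0 TPM in the others.

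At 26 °C the early endosperm also had more genes higher than lower. On day 1, 937 genes were higher and 349 lower than at 16 °C, on day 3 there were 1234 and 466, and on day 7 there were 1599 and 546. Median centring gave 690 and 487, 970 and 675, and 1046 and 1037. Rescaling without the 10 most abundant genes gave 1367 and 816 on day 7. Bo4g163690 itself was at 129267 TPM at 26 °C and 220613 TPM at 16 °C on day 7. Bo3g044590, also among the 2 genes with the largest excess in embryo, was at 118 TPM at 26 °C and 0.43 TPM at 16 °C in endosperm on day 1, and at 240.5 and 0.83 TPM on day 3. Bo5g127240 was at 122 and 0.35 TPM on day 3. Bo9g169340 was lower at 26 °C on that day, at 1.94 against 67.5 TPM. On day 7, Bo5g094620 was at 161 TPM at 26 °C and 2.71 TPM at 16 °C, and Bo4g195870 at 11.9 and 142 TPM.

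The late endosperm differed more widely. On day 15, 1755 genes were higher at 26 °C and 1305 lower, which turned to 1517 and 1575 after median centring. In the column labelled 26 °C on day 18, 1685 were higher and 1763 lower than at 16 °C, which turned to 1759 and 1639 after centring and to 2178 and 1868 after rescaling. On day 22 there were 3779 and 2832, which is 6611 of the 14601 genes. Median centring made this 4051 and 2561, and rescaling made it 3394 and 3923. By comparison, 344 genes separated the 16 °C columns of days 15 and 18, and 1006 those of days 18 and 22. Bo9g026030 was at 1853 TPM at 26 °C and 11.4 TPM at 16 °C on day 15. Bo2g131820, which was lower late at 16 °C, was at 4.60 TPM at 26 °C and 384 TPM at 16 °C on day 15. On day 22, Bo9g171260 was at 539.5 TPM at 26 °C and 1.77 TPM at 16 °C, and Bo5g145530 at 508 and 1.68 TPM. On the same day Bo4g192910 was at 1.26 TPM at 26 °C and 880.4 TPM at 16 °C, and Bo2g164020 at 0.53 and 252 TPM. Of the 425 genes at least 4-fold higher at 16 °C on day 22 than on day 7, 342 (80.5%) were 2-fold higher at 26 °C on day 15 and 10 lower. Of the 297 genes at least 4-fold lower, 165 (55.6%) were lower at 26 °C on day 15 and 3 higher. Of the 7052 genes within 0.5 log2 units between days 7 and 22, 627 (8.9%) were higher and 324 (4.6%) lower. On the 16 °C course of days 0 to 3, the endosperm column of day 1 at 26 °C lay at 1.63, with a range of 0.38 to 1.87 that spans its own day, and that of day 3 at 2.904, with a range of 2.6 to 3, where this course ends. On the course of days 7 to 22, the column of day 7 at 26 °C lay at day 10.5, with a range of 9.98 to 10.95, and those of days 15, 18 and 22 lay at its end. The temperature difference of day 22 minus that of day 7 was 2-fold upward for 3053 genes and downward for 3390, or 4209 and 2362 after median centring.

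Many genes differed by temperature in the same direction in both tissues. On day 1, 427 genes were higher at 26 °C in both embryo and endosperm, where independent lists would share 86.4, and 65 were lower in both, where independent lists would share 8.58. None was lower in embryo and higher in endosperm, and 8 were the reverse. On day 22, 1445 genes were higher in both tissues, against 640.4 for independent lists, and 839 lower in both, against 342. The log2 differences of the 2 tissues correlated across genes with Pearson's r of 0.62 on day 1, 0.61 on day 3, 0.42 on day 7, 0.40 on day 15, 0.39 on day 18 and 0.63 on day 22. From day 7 on, the endosperm libraries used the Ovation kit and the embryo libraries the standard one. The lower r of days 7, 15 and 18 came with this change of kit, but r was 0.63 on day 22 with the same kits. The day 18 value uses the endosperm column labelled 26 °C, and was 0.58 with the column labelled recovery in its place. Genes are not independent replicates, and the tables list genes that the authors selected.

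Recovery seeds were compared with both temperatures. In embryo the recovery columns differed in fewer genes from 26 °C than from 16 °C. On day 18, 257 genes were higher and 436 lower in recovery than at 26 °C, or 513 and 399 after rescaling without the 10 most abundant genes. On day 22 the numbers were 318 and 130, or 559 and 69 after rescaling. Against 16 °C, 818 genes were higher and 1228 lower on day 18, and 2189 were higher and 1091 lower on day 22. Median centring made the latter 1344 and 1688, and rescaling made it 1823 and 1759. Bo6g119840 was at 0.27 TPM in recovery, 49.4 TPM at 26 °C and 31.7 TPM at 16 °C on day 18. Bo3g035510 was at 2234 TPM in recovery and 10.6 TPM at 16 °C on day 18. The 1240 embryo genes that were higher at 26 °C on day 15 had a median fold over 16 °C of 2.29 at 26 °C and 1.77 in recovery on day 18, and of 3.02 and 2.38 on day 22. For the 1715 genes that were lower on day 15, the median log2 difference from 16 °C was -1.22 at 26 °C and -0.97 in recovery on day 18, and -0.96 and -0.79 on day 22. Both differences use the same 16 °C column.

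In endosperm the distances from 16 °C of the day 18 columns labelled 26 °C and recovery were ordered the other way. The column labelled recovery differed from the column labelled 26 °C in 4508 genes, 3237 higher and 1271 lower. Median centring made this 2426 and 1841, and rescaling made it 2668 and 2399. It also lay further from 16 °C, with 3983 genes higher and 2572 lower, or 3398 and 3208 after centring and 3724 and 3542 after rescaling. The 1755 genes that were higher at 26 °C on day 15 had a median fold over 16 °C of 2.299 in the column labelled 26 °C and 3.89 in the column labelled recovery. On day 22 the recovery and 26 °C columns were close, with 501 genes higher and 321 lower in recovery, and the same genes had a median fold over 16 °C of 2.03 at 26 °C and 1.97 in recovery. Against 16 °C on day 22, recovery had 3160 genes higher and 2476 lower. Median centring made this 3511 and 2154, and rescaling made it 3182 and 3312. On day 22 Bo1g094210 was at 1.92 TPM in recovery and 126 TPM at 26 °C, and Bo5g109950 was at 96.6 and 3.79 TPM.

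**Figure D5:**
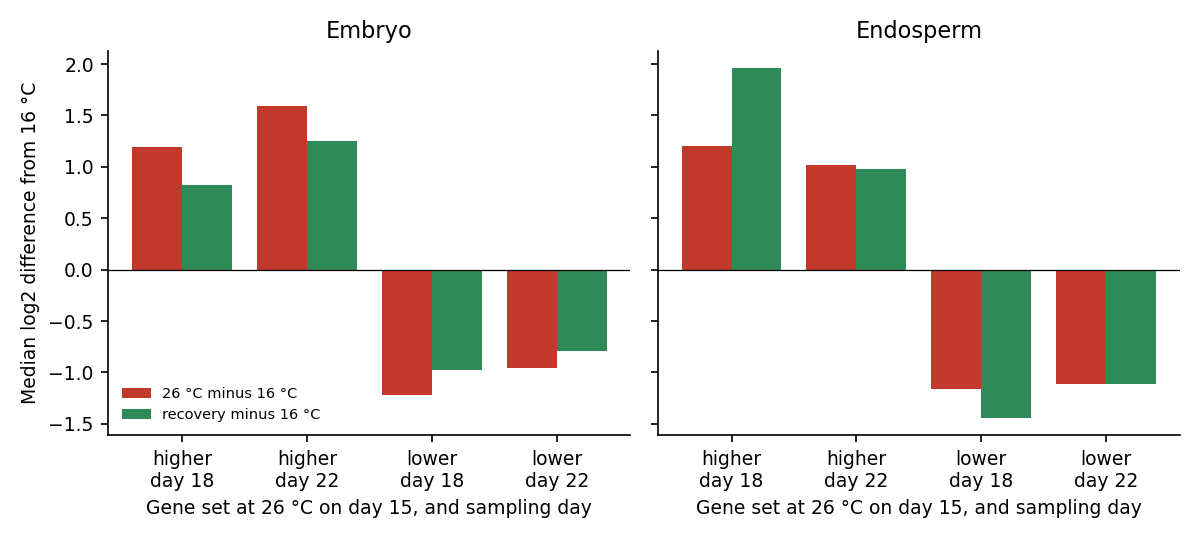
Median log2(TPM + 1) difference from 16 °C, on days 18 and 22, of the genes that were higher or lower at 26 °C on day 15, in the 26 °C column (red) and the recovery column (green) of embryo and endosperm as labelled. On day 18 the median of the higher genes is 1.19 at 26 °C and 0.83 in recovery in embryo, and 1.201 and 1.96 in endosperm.

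In the endosperm hour series, the temperature difference widened from hour 1 to hour 72. At hour 1, 1481 of 13203 genes were higher at 26 °C and 1174 lower. At hour 24 the numbers were 2214 and 940, and at hour 72 they were 2911 and 1727. Of the genes higher at hour 24, 894 were also higher at hour 72, where independent lists would share 488. Of the genes lower at hour 24, 502 were also lower at hour 72, where independent lists would share 123. Between hours 1 and 24, 4858 genes differed at 16 °C and 5742 at 26 °C. Between hours 24 and 72 the numbers were 2739 and 6407. Bo8g095500 was at 0.50 TPM at 26 °C and 69.03 TPM at 16 °C at hour 1. Bo1g050780, which was higher at 26 °C in both tissues on days 1, 3, 7, 15 and 22, was at 54.7 TPM at 26 °C and 926 TPM at 16 °C at hour 1, and at 2.11 and 98.2 TPM at hour 24. At hour 72, Bo5g042760 was at 774 TPM at 26 °C and 3.19 TPM at 16 °C, and Bo5g057370 at 309 and 0.70 TPM. Bo5g145530 was at 1.84 TPM at 26 °C and 491 TPM at 16 °C at hour 72. Bo4g191670 was at 4.27 and 603 TPM. Placed on the 16 °C series, the 26 °C column of hour 1 lay at hour 4.36 and that of hour 24 at hour 37.9, with a range of 33.3 to 41.3 over 10 random subsets of the genes. That of hour 72 lay at the end of the series.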

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

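All tests here of the columns labelled 26 °C and recovery on day 18 were chosen after the values of those columns had been seen. For the exchange between tissues and the rescaling, the outcome that would count for or against was written down before that result was computed. The difference between tissues itself was not tested, since each group has 1 value. On day 18 the recovery column moved towards 16 °C in embryo and away from it in endosperm. Among the genes higher at 26 °C on day 15, the median log2 difference of recovery minus 26 °C was -0.37 in embryo and 0.69 in endosperm. Among the genes lower on day 15 it was 0.25 in embryo and -0.23 in endosperm.

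A few genes taking most of the TPM do not account for the endosperm order: after rescaling without the 10 most abundant genes, the column labelled recovery lay 1.63 log2 units (root-mean-square) from 16 °C and the column labelled 26 °C 1.09. An exchange of the 2 endosperm columns of day 18, in the tables or earlier, is a candidate explanation. Without rescaling, the 26 °C column of day 15 lay 0.68 log2 units from the column labelled 26 °C and 1.11 from that labelled recovery. Embryo had the reverse order, at 0.73 and 0.55. The endosperm 26 °C column of day 22 lay 1.30 and 0.83 from the same columns, against 0.78 and 1.09 in embryo. The endosperm recovery column of day 22 lay 1.08 and 0.74 from them, against 0.62 and 0.85 in embryo. Held against embryo, these orders are the ones an exchange would give. By nearness alone, those of the day 15 column and of recovery on day 22 go with the labels. The distances use the day 18 columns that raised the question, so they are not separate support. With the 2 endosperm columns of day 18 exchanged, the 26 °C minus 16 °C differences of embryo and endosperm correlated across genes at 0.58. As labelled the value was 0.39. The same exchange on day 22 lowered it from 0.63 to 0.58. That is a weak control, since those columns differed in 822 genes, against 4508 on day 18. With embryo recovery in place of embryo 26 °C, the endosperm column labelled 26 °C on day 18 gave 0.37. This is slightly below 0.39, where an exchange might lead to a higher value. The embryo recovery and 26 °C columns of day 18 differed in 693 genes, so this replacement could move the value little and decides nothing. The recovery minus 26 °C differences of days 18 and 22 correlated with r of -0.33 in endosperm and 0.53 in embryo. An exchange would turn the sign in endosperm by construction. This value largely restates the order of the day 18 columns that raised the question, so it is not separate support. A response of the endosperm to the return to 16 °C stays open, since recovery on day 22 lay 1.30 from 16 °C and the 26 °C column 1.49, which neither requires nor excludes it.

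In endosperm, the temperature difference at hour 72 ran against that of day 22, with a correlation across genes of -0.35; the difference between these times was not tested. Of the genes higher at 26 °C on day 22, 871 were lower at 26 °C at hour 72, where independent lists would share 444, and 427 were higher, where they would share 661. The sets were made with different library kits.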

How the results depend on the processing

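No paired analysis was possible because the deposited tables hold 1 value per group and no replicate numbers. For the same reason the replicate block, the fit on 2 groups alone, the other number of tests for the Benjamini-Hochberg adjustment, leaving out each replicate and the gene list tests were not run. The rescaling, the exchange of columns, and the positions and recovery medians were chosen after seeing the data. All 28 counts of genes stayed within 1.5 times of their value with median centring and with rescaling, although the split between higher and lower moved as given in the report. Leaving out the filter says nothing about counts between 2 columns, recovery medians or identifiers, since a gene under 1 TPM in every column cannot differ 2-fold on this scale. It could move the positions and the 2 counts of a difference between temperature effects, which became 4898 in embryo and 6520 in endosperm, against 4888 and 6443. The 5 positions that were rerun stayed within 1.5 times under the 4 settings. The 16 recovery medians did so, with the same sign, under the other 3. Even so, the embryo position of day 3 moved past its own day, from 2.79 to 4.14 with median centring and to 3.63 with rescaling. Of 104 identifiers and comparisons, 7 moved by more than 1.5 times with a pseudocount of 0.1 and none changed sign; under rescaling 3 could not be given a value, since those genes were among the ones left out.

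With a pseudocount of 0.1, 19 counts of genes were over 1.5 times higher, because genes with low values then pass the 2-fold rule. For 26 °C against 16 °C in embryo they were 2726 on day 1, 1641 on day 3, 2651 on day 7, 5618 on day 15 and 6489 on day 18. In endosperm they were 2147 on day 1, 2654 on day 3, 3691 on day 7, 4996 on day 15, 5754 on day 18, 4664 at hour 1 and 4999 at hour 24. Embryo recovery gave 1911 against 26 °C and 4465 against 16 °C on day 18, and 1293 and 5677 on day 22, and endosperm recovery gave 2053 against 26 °C on day 22. Endosperm at 16 °C gave 641 for day 3 against day 0 and 5376 for day 22 against day 7. With the endosperm columns of day 18 exchanged, 26 °C against 16 °C gave 6555 genes, recovery against 16 °C gave 3448, and recovery against 26 °C gave 4508 with the directions reversed. Depth is unknown, so how far it limits the low values was not tested.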

Other observations

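The tests here set before their results were seen are the direction of the day 7 genes, the embryo check of the library kit with a pseudocount of 1 and the median at hour 72; the others were chosen after the result was seen. Genes found at 26 °C and hardly at 16 °C far outnumbered the reverse, by a rule that does not treat the 2 temperatures alike. The 26 °C columns of days 18 and 22 lay at the end of the 16 °C course, so genes gained late could pass as found at 26 °C alone. A gene lost late is likely to be at 1 TPM or more in an early 26 °C column, and then cannot pass the reverse. In embryo, 90 genes reached 5 TPM at 26 °C and stayed under 1 TPM in all 7 columns at 16 °C, and 82 of them had their highest 26 °C value on day 22. Only 3 embryo genes did the opposite. In endosperm the numbers were 52 and 8 on days 0 to 3, 285 and 12 on days 7 to 22, and 248 and 8 in the hour series. Among these, Bo3g167210 was at 124 TPM in embryo at 26 °C on day 22 and at most 0.58 TPM at 16 °C, and Bo4g187850 was at 262 TPM in endosperm at 26 °C on day 22 and at most 0.94 TPM at 16 °C on days 7 to 22; both were chosen after their values were seen.

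Bo5g145530 differed by temperature in opposite directions on day 22 and at hour 72, in series whose clocks the labels do not tie together. In embryo it was at 371 TPM at 26 °C and 18.2 TPM at 16 °C on day 15, and at 1644 and 159 TPM on day 22. In endosperm it was at 508 TPM at 26 °C and 1.68 TPM at 16 °C on day 22, and at 1.84 and 491 TPM at hour 72. In the endosperm columns of day 18 it was at 5.94 TPM in the one labelled 26 °C and at 244 TPM in the one labelled recovery. Bo1g050780 was higher at 26 °C in the day series of both tissues, at 7.68 against 0.07 TPM in embryo and 17.1 against 0.08 TPM in endosperm on day 1, and lower at 26 °C in the hour series of endosperm. In endosperm on day 18 it was at 0.04 TPM in the column labelled 26 °C and listed at 0 at 16 °C. Both genes were followed across columns after their values were seen.

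In both tissues the 26 °C columns of days 7 and 15 were placed later on the 16 °C course than their own day, although for endosperm on day 7 the nearest single 16 °C column was that of day 7. As the whole cause, faster progress along that course is argued against for embryo on day 7: 1.29% of genes lay 2-fold outside the course at 26 °C (1.16% to 2.39% over all settings), against 0% and 0.017% for the 16 °C columns of days 7 and 15. For day 15 it stays open, since the 3.02% outside was less than the 4.87% of the 16 °C column of day 22, at the end of the course. A few genes taking most of the TPM are argued against by the position of the embryo column of day 7, which was 11.37 after rescaling without the 10 most abundant genes. Faster progress as part of the cause may stand. Of the genes 2-fold apart on day 7 after median centring, 78.9% of 1218 in embryo and 78.3% of 2083 in endosperm lay in the direction of the later 16 °C difference from day 15 to day 22, where independent directions would give 50.8% and 50.02%.

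In endosperm, 9 genes were at least 16-fold higher in every Ovation column than in any other endosperm column, and 0 were as much lower. Embryo used 1 kit, so a kit step should be missing there. Of the 7 genes listed in embryo, 1 (14.3%) was 4-fold higher late than early with a pseudocount of 1, under the 20% set beforehand for a kit effect, but 3 were with 0.1 and 4 with none, because their embryo values are low. The check therefore decides nothing, and with kit and day changing together, library kit and seed development cannot be told apart for these genes.

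For the opposite temperature differences of day 22 and hour 72 in endosperm, one hypothesis is that transcripts gained late in the day series are lost sooner at 26 °C in the hour series. The 292 genes that were 4-fold higher at 16 °C on day 22 than on day 7 and were kept in the hour series had a median log2 difference of -1.52 at hour 72, with 165 genes 2-fold lower at 26 °C and 47 higher. Their median was -0.34 at hour 24 and -0.01 at hour 1. The result is one that the hypothesis would give, but the genes were not followed over the hours at each temperature, so no loss was measured. The hour series and days 7 to 22 also differ in library kit, and the labels do not tie the clocks of the hour and day series together. At 16 °C, 2739 of 13203 genes differed between hours 24 and 72. Between days 1 and 3, made with the same standard kit, 278 of 12604 did. Hours 24 and 72 are therefore not read as days 1 and 3.

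Neighbouring identifiers shared a direction more often than shuffled values did. On day 22, of the 3049 pairs of consecutive identifiers in embryo, 360 were 2-fold apart in the same direction at both members, against a mean of 274 and a highest of 320 in 1000 shuffles. In endosperm, 554 of 4533 pairs were, against a mean of 474 and a highest of 530. The share of endosperm genes listed at 0 was between 10.3% and 13.8% in the 3 columns of day 18 and between 0.5% and 6.4% in the other columns of days 7 to 22.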
